A study of Mus musculus with 14 samples.

How the data were processed

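H3K4me3 ChIP-seq libraries of mouse prefrontal cortex were compared between control mice (3 libraries), mice after 10 days of social defeat (SDS10, 5 libraries) and mice after 30 days (SDS30, 5 libraries), grouped by the labels. Per the labels' protocols, chromatin was cut with micrococcal nuclease to mononucleosomes, immunoprecipitated with an H3K4me3 antibody, amplified with 6 to 8 PCR cycles and sequenced as single reads of 100 bp. Per the submitters' processing notes, Trimmomatic, Bowtie2, MACS2 and DESeq2 were used with the builds mm10 and GRCm38.p5; their versions, roles and settings are not given in the sources used here. The deposited table holds 1 row per peak summit of a peak set shared by all libraries, with a normalised signal per library made by the authors by dividing reads by 1 size factor per library. The size factor was inferred from the values: 100% were whole multiples of the library's smallest step (tolerance 0.001 reads), which gave the reads back. The deposited peak score (1.30 to 11025, scale not given in the sources used here) was not used in a test. How duplicates were treated and the window around a summit in which reads were counted are not given in the sources used here. Neighbouring summits lie 199 bp apart in the median, so a nucleosome-sized fragment can fall on more than 1 row and neighbouring rows are not independent. The input library was not analysed here, so enrichment over input is not reported. Reads without molecular identifiers are not independent molecules.

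Because the values are normalised, the test was limma (version 3.58.1) on log2(value + 1) with a trend in the variance. The plan fixed before the data were examined named this test for normalised values and a count test in edgeR for counts. Fold changes are on that scale, which understates the change of low summits. Summits were kept by edgeR's filterByExpr on the recovered reads (152270 kept, 937 left out). All 13 libraries entered a single fit with a mean per group and no covariate, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. edgeR (4.0.16) on the recovered reads called 0 summits in each comparison; DESeq2 (1.42.0) was run as an alternative in R 4.3.3. On simulated counts for the 152270 summits with 200 changed by 2-fold, limma recovered 38.5% in SDS10 against control, 33% in SDS30 against control and 55% in SDS30 against SDS10, and 85%, 80.5% and 94% of those changed by 3-fold.

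Summits are given at the coordinates of the deposited table, on mm10. Genes came from a RefSeq gene table of the same primary assembly (GRCm38.p6). It gives gene boundaries without strand, exons or introns, so a start site cannot be told from a gene's end: a gene's summit is the strongest within 2 kb of either boundary, internal promoters are not seen, and neighbouring genes can share a summit. All 605 gene symbols listed by name were matched. Of the tested summits, 111390 (73.2%) lie within 2 kb of a gene boundary. The 27 gene lists, covering cell types, neuronal signalling, stress, chromatin and housekeeping functions, were tested with limma's camera (preset correlation 0.01), with an estimated correlation, with fry and with an exact permutation of each list's mean per library. Peak widths are not in the table, so wide regions were taken as the 5% of summits in regions with the widest span of summits. Named genes followed a rule fixed before the data were examined: the 8 largest changes per direction past the threshold with groups that do not overlap, and where fewer than 4 passed, the 4 protein-coding genes with the smallest p-values per direction; up to 4 members of each called list; 14 fixed genes; and the 2 summits beyond 2 kb with the smallest p-values per direction. Gene models, olfactory and vomeronasal receptors and pseudogenes were left out of the ranking. Some of the genes and summits that the rule takes are not reported here.

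Alternatives were other scaling factors, filters, tests, pseudocounts, distances, covariates, a replicate block and leaving out each library in turn; their effect is in the closing section. Library measures were compared with exact permutation tests. Correlations over the 13 libraries used 100000 permutations, so that 1e-05 is the smallest p they can give. No correction for GC content was run, since a genome sequence was not used here.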

Results

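H3K4me3, a histone mark found at the start of active and poised genes, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in the prefrontal cortex of adult male C57BL/6J mice aged 10 to 12 weeks. Social defeat stress was a daily encounter with an aggressive CD1 mouse followed by housing beside it. The series holds 3 control libraries, 5 libraries after 10 days of defeat (SDS10), 5 after 30 days (SDS30) and 1 input library, which was not analysed here. Tissue was taken 24 hours after the last session. The deposited table gives a normalised read count for 153207 peak summits in 48695 called regions in each of the 13 ChIP libraries. Between 4512817 and 10887911 reads fell on these summits per library. SDS10 replicate 4 was the shallowest and control replicate 1 the deepest. Total reads were 8778700 ± 2122700 (SD, n = 3) in control, 7387000 ± 2192800 (SD, n = 5) in SDS10 and 8201700 ± 2280900 (SD, n = 5) in SDS30. The labels number the libraries within a group but do not say that each came from a separate animal, so p-values measure the spread between these libraries. All libraries carry the same batch date.

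In the control cortex, the mark was strongest at several lists of genes of basic cell functions and weaker at markers of cell types. Differences between lists were not tested. A tested summit lay within 2 kb of a boundary of 14237 protein-coding genes, and the strongest such summit of each gene had a median normalised count of 97.1 ± 0.784 (SD, n = 3). Nuclear-encoded genes of oxidative phosphorylation had a median of 119.9 ± 6.27, cytosolic ribosomal protein genes 116 ± 1.32, the enzymes and subunits that write, remove or read H3K4 methylation 113 ± 2.79, and heat shock and chaperone genes 109 ± 3.93 (SD, n = 3 each). Core and linker histone genes were an exception, with a median of 47.2 ± 4.29 (SD, n = 3), near the markers of cell types. Activity-regulated genes, such as Fos and Arc, stood at 91.3 ± 7.02, and glucocorticoid-responsive and stress-axis genes at 91.5 ± 6.12. Excitatory neuron markers had a median of 53.7 ± 5.43, inhibitory neuron markers 43.1 ± 2.51, oligodendrocyte and myelin genes 46.2 ± 1.65, astrocyte markers 67.1 ± 3.52 and endothelial and mural cell markers 43.9 ± 6.52. Developmental transcription factors, of which 79 of 118 had a summit (34 of the Hox, Pax, Gata and Lhx families and 45 of the Nkx, Tbx, Sim, Irx, sine oculis homeobox and Fox families), had a median of 31.2 ± 0.889, and clustered protocadherins 29.3 ± 1.91. Only 16 of 36 microglia and macrophage markers had a summit.

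The comparison of SDS10 with control asked what 10 days of defeat did to the mark. As groups, 2 of the 27 gene lists were called in SDS10, both lower relative to other genes. Oligodendrocyte and myelin genes had a mean log2 fold change of -0.16, with 19 of 27 members lower (limma's camera, adjusted p = 0.0136; adjusted p = 0.293 with an estimated correlation). Their score, the list's mean log2 value centred over all libraries, was -0.0745 ± 0.0708 (SD, n = 5) in SDS10 and 0.0885 ± 0.0393 (SD, n = 3) in control (exact permutation test, two-sided, p = 0.0357, adjusted p = 0.723 over 27 lists). With 56 splits no list alone could pass over 27 lists, so the adjusted value decides little. The exact p was 0.0952 without control replicate 1 or 2 (21 splits) and 0.0571 without SDS10 replicate 1, 4 or 5 (35 splits). The score difference, -0.163 with all libraries, stayed between -0.184 and -0.144 without any 1 library. Among the members with the smallest p-values were Mal (44.9 ± 12.9 against 65.8 ± 15.9), Ppp1r14a (56.9 ± 16.4 against 78.1 ± 7.91) and Myrf, a transcription factor of myelination (53.1 ± 7.22 against 72.6 ± 11.1). The log2 fold change of Ppp1r14a was -0.51, and -0.278 without SDS10 replicate 2. Developmental transcription factors had a mean of -0.12, with 52 of 79 lower (adjusted p = 0.0136; adjusted p = 0.952 with an estimated correlation). The mean was -0.16 over the 45 Nkx, Tbx, Sim, Irx, sine oculis homeobox and Fox factors, 31 of them lower, and -0.057 over the 34 Hox, Pax, Gata and Lhx factors, 21 of them lower, a division made after the values were seen and not tested. The smallest p-values were at Six5, Nkx2-3, Tbx21 and Foxa1, with log2 fold changes of -0.49, -0.92, -0.52 and -0.59. Both calls were lost without control replicate 1, where the means were -0.144 and -0.0575, and without SDS10 replicate 2, where they were -0.145 and -0.0671. With loess offsets, which remove trends with the level, both calls were lost at means of -0.161 and -0.106. No member of any list passed, whether adjusted over all summits or adjusted over the list alone. Activity-regulated genes (mean 0.05), excitatory neuron markers (mean 0.01), glucocorticoid-responsive genes (mean -0.02) and the H3K4 methylation machinery (mean 0.02) were not called, and ependymal and choroid plexus markers (mean -0.16) missed the threshold (adjusted p = 0.0518). Core and linker histone genes had a mean of 0.11, with 48 of 63 higher, and were not called (adjusted p = 0.1001).

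**Figure D1:**
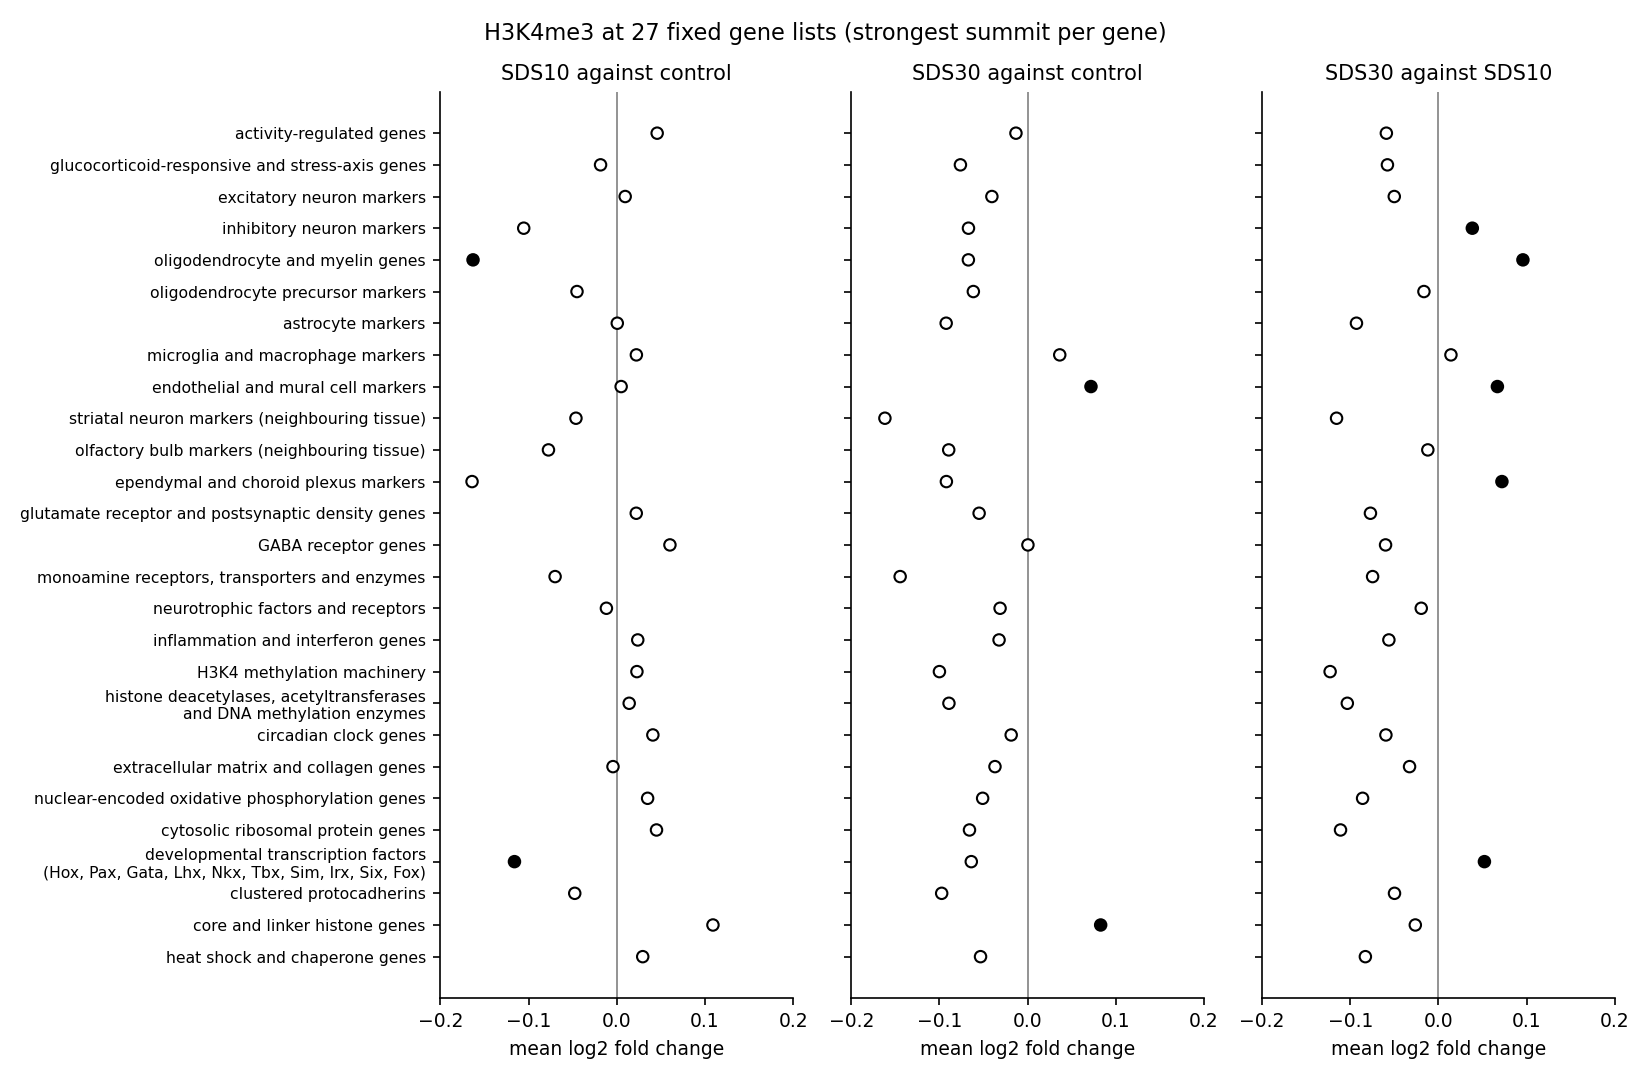
Mean log2 fold change of H3K4me3 (horizontal axis) over the members of 27 gene lists (vertical axis), 1 strongest summit per gene, in the 3 comparisons (panels); filled points were called by camera with a preset correlation, open points were not. The means lie between -0.164 and 0.109 in SDS10 against control, and no call held with an estimated correlation.

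Among each gene's strongest summit within 2 kb of its boundaries, those nearest to a call in SDS10 did not pass the test (adjusted p = 0.9999 for each in limma). On the higher side stood Iqcj (chromosome 3, 68056692 to 68056693), at 63.5 ± 26.6 (SD, n = 5) against 27.7 ± 13.4 (SD, n = 3) in control, a log2 fold change of 1.19 ± 0.28 (SE). Npy1r, which encodes the Y1 receptor for neuropeptide Y (chromosome 8, 66697294 to 66697295), was at 56.4 ± 6.75 against 31.4 ± 10.5. Cldn12, a claudin gene (chromosome 5, 5514293 to 5514294), was at 93.3 ± 17.6 against 56.3 ± 5.17, and Ing5, which encodes a reader of H3K4me3 in histone acetyltransferase complexes (chromosome 1, 93804121 to 93804122), at 116.5 ± 24.1 against 77.0 ± 3.87. On the lower side were Vkorc1l1 (chromosome 5, 129942464 to 129942465), at 63.7 ± 9.07 against 95.7 ± 11.3, and the proton channel gene Otop1 (chromosome 5, 38277790 to 38277791), at 11.5 ± 4.18 against 25.3 ± 5.67. Rftn1 and Camsap3 followed, with log2 fold changes of -0.51 ± 0.17 and -0.55 ± 0.18 (SE). Groups did not overlap at 424 of 14237 genes (2.98%), where chance gives 3.57%. Beyond 2 kb of any gene boundary, summits with the smallest p-values lay inside Kcnj3 (chromosome 2, 55438717 to 55438718; 24.8 ± 6.11 against 8.13 ± 3.86) and Lrrc4c (chromosome 2, 97472193 to 97472194; 28.8 ± 7.57 against 10.97 ± 3.54), both higher, and inside Speg (chromosome 1, 75381538 to 75381539; 15.2 ± 3.46 against 35.5 ± 5.34), lower, again without passing the test.

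In SDS10 against control, no summit passed an adjusted p of 0.05 in limma among 152270 tested, and 4891 had an unadjusted p under 0.05. DESeq2 and edgeR's quasi-likelihood test also called 0, with 5419 and 4599 at an unadjusted p under 0.05. The median 95% interval of a log2 fold change reached 0.529 to either side, and for 83.5% of summits the interval lay inside -1 to 1. When known changes were put into the real reads, 24% of 200 summits changed by 2-fold and 80% of those changed by 3-fold were recovered, so changes of under 2-fold were mostly not detectable at this depth and number of libraries.

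The 14 genes fixed in advance all had a summit, and none passed in either comparison with control. In SDS10, 5 were higher and 9 lower, with the largest log2 fold change at Gad1 (0.38 ± 0.33 SE), the gene for a GABA-synthesising enzyme, which was at 0.146 without control replicate 1. The immediate early genes gave 101 ± 12.7 (SD, n = 5) in SDS10 against 85.6 ± 11.9 (SD, n = 3) in control for Fos, 129 ± 15.9 against 118 ± 12.8 for Egr1, 77.0 ± 14.2 against 86.3 ± 12.2 for Arc and 26.3 ± 3.02 against 22.9 ± 6.37 for Npas4. Bdnf had a log2 fold change of 0.26 ± 0.29 (SE), and of 0.048 without SDS10 replicate 2. Among stress-axis genes, the values were -0.12 ± 0.33 for the glucocorticoid receptor gene Nr3c1, -0.05 ± 0.19 for its co-chaperone gene Fkbp5, -0.01 ± 0.18 for Sgk1, -0.21 ± 0.25 for Crh and -0.17 ± 0.29 for Crhr1. Mbp (-0.21 ± 0.18), Slc17a7 (-0.35 ± 0.23) and the H3K4 demethylase gene Kdm5b (-0.23 ± 0.17) did not pass either.

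**Figure D2:**
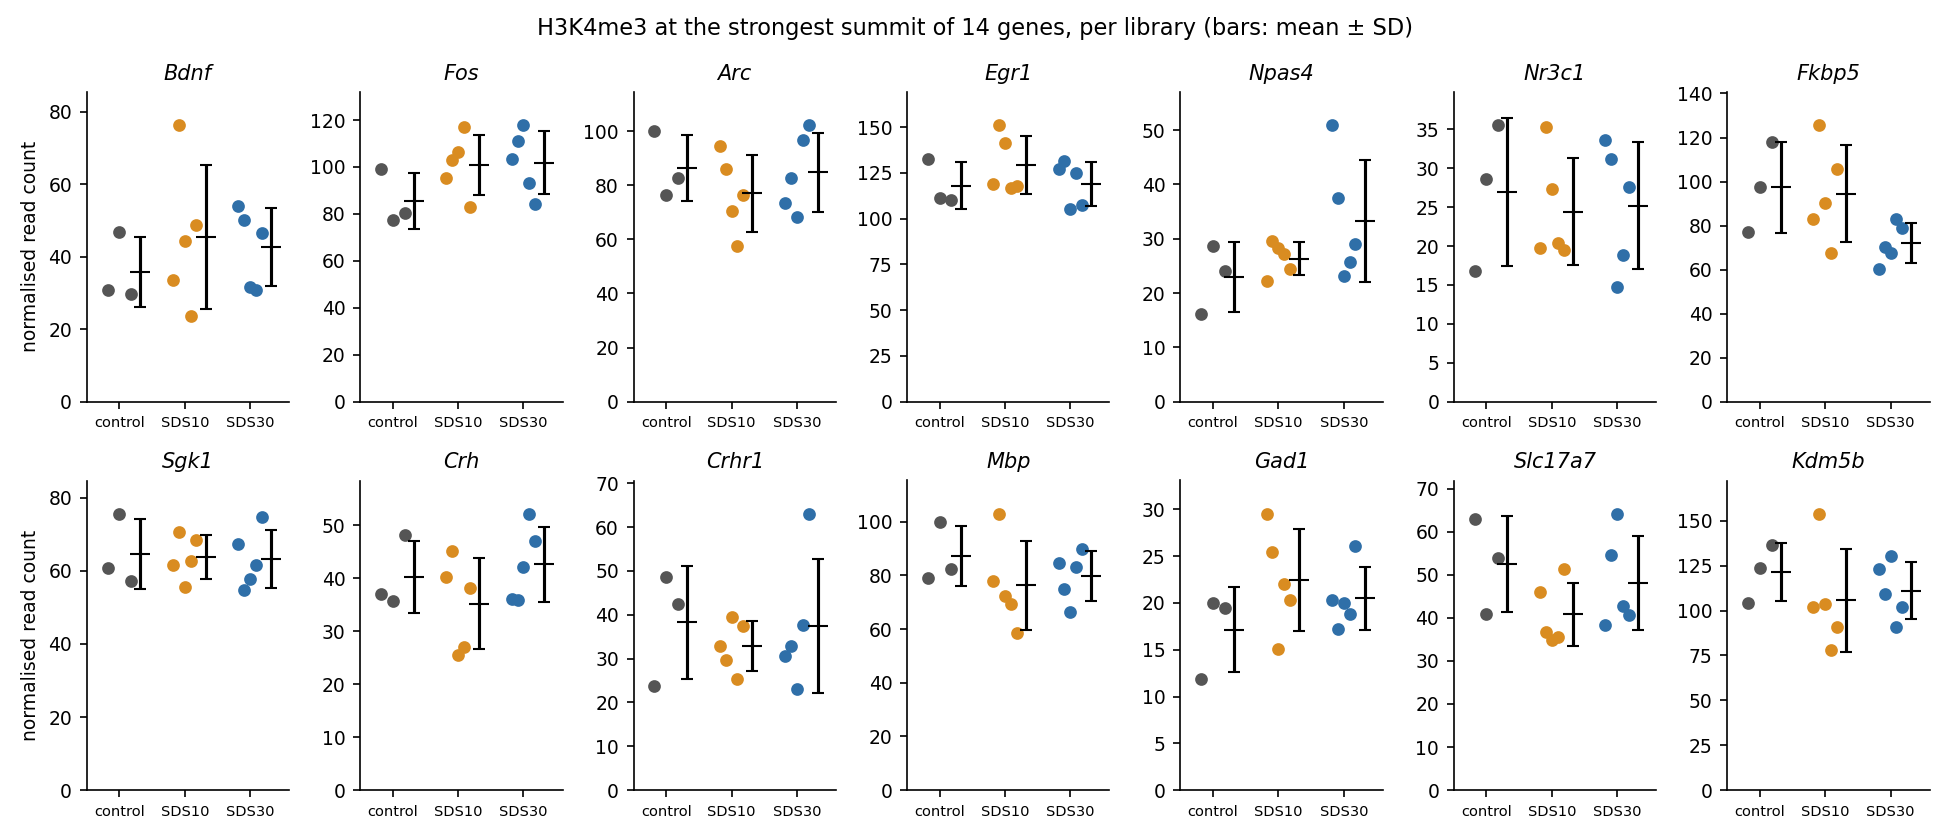
Normalised read count at the strongest summit of 14 genes (vertical axis, from 0) in each library of the control (n = 3), SDS10 (n = 5) and SDS30 (n = 5) groups; points are libraries and bars the mean ± SD. The groups overlap at every gene, Fkbp5 included, where SDS30 has 72.0 ± 9.10 and control 97.4 ± 20.6.

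The comparison of SDS30 with control asked the same after 30 days. Core and linker histone genes were called higher relative to other genes in SDS30, with a mean log2 fold change of 0.08 and 42 of 63 members higher (camera adjusted p = 0.000168; adjusted p = 0.649 with an estimated correlation). The same list had a mean of 0.11 in SDS10, and its difference between the durations was not called (mean -0.03, adjusted p = 0.104). The call in SDS30 held without any 1 library, but the mean was 0.139 without control replicate 1 and 0.0502 without control replicate 2. The 63 genes share 39 summits. Examples were H2bc7, whose summit also serves H2ac8 and H2bc8 (28.3 ± 9.97 against 15.4 ± 6.75), H3c6 (33.7 ± 7.17 against 24.5 ± 5.56) and, lower, H2ac10 (39.8 ± 7.25 against 51.0 ± 9.80); H3c11 was at 16.8 ± 6.43 against 12.2 ± 6.76. Without 1 library, the log2 fold changes ranged from 0.636 to 1.173 for H2bc7, 0.341 to 0.612 for H3c6, -0.475 to -0.21 for H2ac10 and -0.02 to 0.82 for H3c11. Endothelial and mural cell markers were called higher too, with a mean of 0.07 and 22 of 31 higher (adjusted p = 0.0361; adjusted p = 0.963 with an estimated correlation), and their mean turned to -0.093 without control replicate 2. This call was also lost without SDS30 replicate 2 (0.0763), 3 (0.0244) or 4 (0.0265), and the mean was 0.183 without control replicate 1, 0.126 without control replicate 3 and 0.156 without SDS30 replicate 1. Striatal neuron markers, from a neighbouring tissue, had a mean of -0.16, with 16 of 20 lower, and were not called (adjusted p = 0.894). With loess offsets both list calls were lost, at means of 0.085 for histone genes and 0.0586 for endothelial and mural markers. Members moved both ways: Pdgfrb and Abcc9 had log2 fold changes of 0.36 ± 0.26 and 0.43 ± 0.31 (SE), and Erg and Kcnj8 -0.51 ± 0.32 and -0.29 ± 0.21. Without 1 library these ranged from 0.264 to 0.518 for Pdgfrb, 0.125 to 0.616 for Abcc9, -0.823 to -0.319 for Erg and -0.411 to -0.18 for Kcnj8. Camera compares a list's t-statistics with those of all other genes, whose median log2 fold change was -0.0716 here. In 16 of the 27 lists the test's direction differed in sign from the mean, as for activity-regulated genes (mean -0.01, test upward, not called). That median does not account for all of them. Olfactory bulb markers, ependymal markers and clustered protocadherins tested upward, without a call, at means of -0.089, -0.092 and -0.097. The test's direction is thus not a statement about the mean fold change.

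Among each gene's strongest summit within 2 kb, the lowest p-value (adjusted p = 1 for each summit named here, in limma) was at a summit shared by Sart3, a spliceosome recycling factor, and Iscu, an iron-sulfur cluster scaffold (chromosome 5, 113771525 to 113771526), with 127 ± 16.4 (SD, n = 5) in SDS30 against 182 ± 13.6 (SD, n = 3) in control and a log2 fold change of -0.53 ± 0.13 (SE). Mast2 (chromosome 4, 116463881 to 116463882; 64.1 ± 13.02 against 103 ± 13.3), Sipa1l2 (chromosome 8, 125569666 to 125569667; 64.1 ± 14.3 against 104 ± 10.1) and a summit shared by Zfp319 and Usb1 (chromosome 8, 95331487 to 95331488; 124 ± 29.0 against 187 ± 25.2) were also lower. On the higher side were Pafah2 (79.5 ± 11.1 against 48.9 ± 14.6), the cyclin B1 gene Ccnb1 (94.4 ± 14.5 against 64.6 ± 7.93), the lysosomal channel gene Mcoln1 (144 ± 9.75 against 108 ± 25.03) and Apom (30.3 ± 8.51 against 15.3 ± 7.56). The log2 fold change of Mcoln1 was 0.43, and 0.26 without control replicate 2. Groups did not overlap at 538 genes (3.78%), where chance gives 3.57%. Away from gene boundaries, the same Kcnj3 summit was at 24.9 ± 8.93 and a summit on chromosome 16 (77595810 to 77595811) at 35.3 ± 9.21 against 15.4 ± 4.10, while summits inside C2cd2 (113 ± 12.0 against 165 ± 16.4) and Runx2 (65.2 ± 13.2 against 110 ± 15.4) were lower, none passing. No summit passed in limma in SDS30 against control, with 5194 at an unadjusted p under 0.05, and DESeq2 and edgeR called 0, with 5763 and 4933 at that level. The interval lay inside -1 to 1 for 85.2% of summits, and 28.5% of 200 summits changed by 2-fold in the real reads were recovered.

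Of the 14 fixed genes, 6 were higher and 8 lower in SDS30. Npas4, an activity-regulated transcription factor, had the largest log2 fold change, 0.50 ± 0.30 (SE), with 33.2 ± 11.3 (SD, n = 5) against 22.9 ± 6.37 (SD, n = 3); it was 0.271 without control replicate 1 and 0.669 without control replicate 2. Fkbp5 was at -0.42 ± 0.19 (-0.577 to -0.271 without 1 library), Fos at 0.25 ± 0.16, Bdnf at 0.23 ± 0.29 and Gad1 at 0.27 ± 0.33. The others lay between -0.13 and 0.08: Slc17a7 (-0.13 ± 0.23), Kdm5b (-0.13 ± 0.17), Mbp (-0.13 ± 0.18), Nr3c1 (-0.10 ± 0.33), Crhr1 (-0.05 ± 0.29), Arc (-0.03 ± 0.18), Sgk1 (-0.03 ± 0.18), Egr1 (0.01 ± 0.14) and Crh (0.08 ± 0.25). The adjusted p was 1 for each in limma.

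The comparison of SDS30 with SDS10 tested whether the durations differed. As groups, 5 lists were called, all higher in SDS30 relative to other genes, whose median was -0.0827. They were developmental transcription factors (mean 0.05, adjusted p = 0.000177), oligodendrocyte and myelin genes (mean 0.10, adjusted p = 0.00209), endothelial and mural cell markers (mean 0.07, adjusted p = 0.00209), ependymal and choroid plexus markers (mean 0.07, adjusted p = 0.0306) and inhibitory neuron markers (mean 0.04, adjusted p = 0.0492). With an estimated correlation their adjusted p-values were 0.487, 0.183, 0.487, 0.183 and 0.487. Myelin genes and developmental factors were also the lists called lower in SDS10 against control. Both comparisons use the same SDS10 libraries, so these calls are not independent of each other. In SDS30 against control neither list was called, at means of -0.067 and -0.064 (camera adjusted p = 0.936 and 0.771). All 5 calls were lost without SDS10 replicate 2, where the means were 0.00331, 0.0775, 0.0065, 0.0583 and 0.0545, and the inhibitory neuron list turned to -0.0151 without SDS10 replicate 4 and to -0.00669 without SDS30 replicate 5. The inhibitory neuron call was also lost without control replicate 2 or 3 (0.0385 each), SDS10 replicate 3 (0.0287) or SDS30 replicate 2 (0.0443). The ependymal call was also lost without SDS10 replicate 4 (0.0585) and without SDS30 replicate 2 (0.0942) or 4 (0.0327). Other means moved by over 1.5 times with the call kept: inhibitory neuron markers without SDS10 replicate 1 (0.0585) or 5 (0.0659), myelin genes without SDS30 replicate 4 (0.0621), endothelial markers without SDS30 replicate 1 (0.151), 3 (0.0194) or 4 (0.0215), and developmental factors without SDS30 replicate 1 (0.152), 2 (0.0310), 4 (0.0311) or 5 (0.0116). Striatal neuron markers had a mean of -0.12, with 16 of 20 lower, and were not called (adjusted p = 0.792). With loess offsets all 5 calls were lost, at means of 0.00276 for developmental factors, 0.0903 for myelin genes, 0.0524 for endothelial, 0.0885 for ependymal and 0.0170 for inhibitory neuron markers. Members moved both ways. Among inhibitory neuron markers Cnr1 was at -0.34 and Npas1 and Pvalb at 0.52 and 0.49. Tspan2 and Fa2h (-0.33 and -0.42) stood against Galnt6 (0.48) among myelin genes, Kdr (-0.23) against Notch3, Abcc9 and Eng (0.42, 0.42 and 0.37) among vascular markers, and Six4 (-0.29) against Six5 and Pax5 (0.40 and 0.78) among developmental factors. Of the ependymal markers, Cfap126, Kl, Rsph1 and Mcidas had 0.22, 0.27, 0.12 and 0.15. Single libraries moved several of these by over 1.5 times. Without SDS30 replicate 2, Kdr was at -0.099, Eng 0.205, Fa2h -0.227, Six4 -0.178 and Mcidas 0.074, and without SDS10 replicate 2, Abcc9 was at 0.225, Pax5 0.46 and Rsph1 0.213. Pvalb was at 0.206 without SDS10 replicate 4 and 0.754 without SDS10 replicate 3, Galnt6 at 0.296 without SDS30 replicate 4, Kl at 0.144 without SDS30 replicate 5, Eng at 0.561 without SDS30 replicate 1 and Mcidas at 0.28 without SDS30 replicate 3. Cytosolic ribosomal protein genes were not called by camera (adjusted p = 0.210), yet 60 of 80 were lower in SDS30, and their score was -0.0579 ± 0.0777 against 0.0531 ± 0.0573 (SD, n = 5 each; exact permutation test, two-sided, p = 0.00794, adjusted p = 0.214 over 27 lists). That exact p is the smallest that 252 splits can give, so no list alone could pass over 27 lists. SDS30 replicate 2, at -0.195 against -0.0412 to -0.00536 in the others of its group, and SDS10 replicate 2, at 0.1465, stood at the ends. The score difference of -0.111 was -0.0767 without the first (exact p = 0.0318), -0.0876 without the second (exact p = 0.0238) and -0.0534 without both (exact p = 0.0286). The H3K4 methylation machinery had 22 of 30 members lower (mean -0.12, exact permutation test, two-sided, p = 0.0397, adjusted p = 0.375) and was not called either. Without SDS30 replicate 2 and SDS10 replicate 2 its score difference was -0.0676 (exact p = 0.143, 70 splits). These libraries hold its lowest and highest scores too (-0.1498 and 0.1942). Leaving out extremes shrinks a difference by itself, so for both lists the smaller difference without the 2 decides little. The exact p of the H3K4 methylation machinery was also above the threshold without SDS10 replicate 2, SDS30 replicate 2 or SDS30 replicate 5 (0.0873 each), SDS10 replicate 1 or 3 (0.0714 each) or SDS30 replicate 4 (0.0794). The score difference of that list, -0.123 with all libraries, stayed between -0.146 and -0.0874 without any 1 library. The exact test uses a list's own mean and is not relative to other genes, whose median was -0.0827. Other lists with control medians above the 97.1 of all protein-coding genes were mostly lower too. Oxidative phosphorylation genes had 58 of 78 lower (exact permutation test, two-sided, p = 0.0476, adjusted p = 0.375). Chaperone genes had 57 of 81 lower, and deacetylases and related enzymes 21 of 27. Whether the ribosomal and H3K4 machinery changes were specific to those lists was not tested. In 15 of the 27 lists the sign of the mean differed from camera's direction.

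Between the durations, no summit passed in limma, and 7795 had an unadjusted p under 0.05, 3061 of them higher and 4734 lower in SDS30. edgeR called 0 with 6838 at that level, and DESeq2 called 0 with 7812. Lower in SDS30 were Reck, an inhibitor of matrix metalloproteinases (chromosome 4, 43875642 to 43875643), at 97.4 ± 8.41 against 141 ± 5.22 in SDS10 (SD, n = 5 each) with a log2 fold change of -0.53 ± 0.11 (SE, adjusted p = 0.963 in limma), the phosphatase gene Ppp6c (chromosome 2, 39226185 to 39226186; 81.2 ± 7.87 against 121 ± 13.6), the actin-capping gene Tmod3 (chromosome 9, 75559517 to 75559518; 109 ± 20.3 against 160.5 ± 21.7) and Zfp280d (chromosome 9, 72275109 to 72275110; 81.6 ± 12.8 against 124 ± 18.7). With DESeq2's filter tuned at its default of 0.1, 4 summits passed in DESeq2 (adjusted p = 0.0467 to 0.0476), those of Reck and Ppp6c and summits at Mmp17 (80.7 ± 9.21 against 122 ± 17.6) and Btbd1 (65.0 ± 14.7 against 113 ± 26.6), the last pair named after their values were seen. Higher in SDS30 without passing were Lgals7 (56.4 ± 15.7 against 29.2 ± 13.1, a log2 fold change of 1.08, or 0.652 without SDS10 replicate 2), the growth factor gene Gdnf (48.2 ± 6.22 against 30.0 ± 9.18), Tmem114 (37.1 ± 6.70 against 21.1 ± 6.61) and Otop1 (23.2 ± 7.15 against 11.5 ± 4.18). Otop1 was also named as lower in SDS10 against control (25.3 ± 5.67 in control), from the same SDS10 libraries. Beyond 2 kb, a summit on chromosome 8 (84198202 to 84198203; 57.4 ± 11.4 against 32.5 ± 1.78) and a summit inside 2310022B05Rik (40.3 ± 7.27 against 21.2 ± 5.69) were higher, and summits inside Pan3 (110 ± 17.2 against 158 ± 12.7) and Fbxo33 (59.8 ± 14 against 97.8 ± 15.9) lower, without passing. Groups did not overlap at 160 genes (1.124%), where chance gives 0.794%.

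By class of summit, the 15227 summits with the highest mean value were lower in SDS30 relative to the rest. Their median log2 fold change was -0.098 against SDS10 (camera adjusted p = 2.95e-13; adjusted p = 0.0464 with an estimated correlation) and -0.080 against control (adjusted p = 2.1e-08; adjusted p = 0.126 with an estimated correlation). Summits over 2 kb from a gene boundary were higher, with medians of 0.054 (adjusted p = 0.00387; adjusted p = 0.0212 with an estimated correlation) and 0.052 (adjusted p = 0.0261; adjusted p = 0.0701 with an estimated correlation). X-chromosome summits were lower in SDS30 than in SDS10 (median -0.068, adjusted p = 0.0261; adjusted p = 0.086 with an estimated correlation). Regions with the widest span of summits were not called in any comparison, and no class was called in SDS10 against control. With loess offsets, the class with the highest values had a mean of 0.00382 against SDS10 (from -0.0987) and 0.00553 against control (from -0.0808). Summits over 2 kb from a boundary lost both calls there, with means of 0.0157 (from 0.0674) and 0.0221 (from 0.063), while the X chromosome kept its call at -0.117 (from -0.0597). Single libraries ended class calls too, and the class with the highest values, called against control without any 1 library, had a mean of -0.0479 without SDS30 replicate 2. Summits over 2 kb from a boundary lost the call against control without control replicate 1 (mean 0.0553) or 2 (0.0574) and without SDS30 replicate 2 (0.0447) or 5 (0.0596), and the call against SDS10 without SDS30 replicate 2 (0.0491). The X chromosome lost its call without SDS10 replicate 2 (-0.0486) or 3 (-0.0557) and without SDS30 replicate 2 (-0.0427) or 5 (-0.05004). Per library, the median centred log2 value of the strongest minus the weakest decile of summits was 0.00654 ± 0.0453 (SD, n = 3) in control, 0.067 ± 0.158 (SD, n = 5) in SDS10 and -0.159 ± 0.166 (SD, n = 5) in SDS30. This strong-minus-weak measure was not among the planned library measures. It restates the class with the highest values in the same data, so it gives no separate support. The difference between durations did not pass after adjustment over the 12 tests of library measures (exact permutation test, two-sided, p = 0.0238, adjusted p = 0.286). With 252 splits no measure alone could pass over 12 tests, however far the groups lay apart, so the adjusted value decides little. The share of reads in the strongest 1% of summits was 3.09% ± 0.0302, 3.14% ± 0.125 and 2.97% ± 0.119, and 99.7% to 99.8% of summits had a read in each library, with no difference past the threshold.

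**Figure D3:**
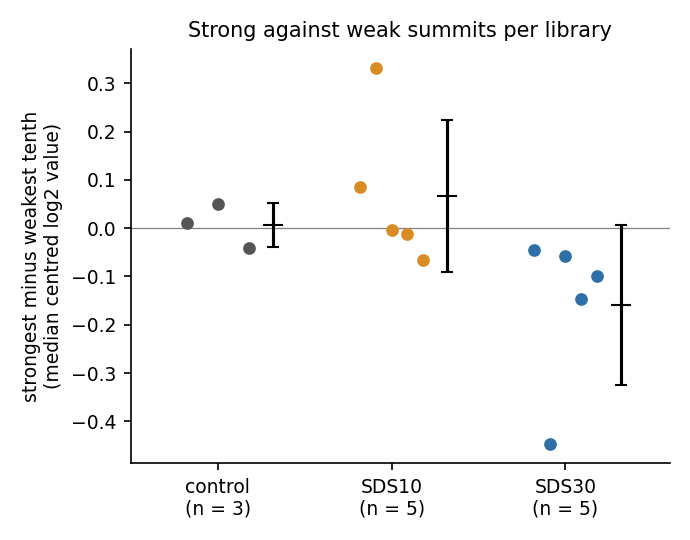
Median centred log2 value of the strongest minus the weakest decile of summits (vertical axis) in each library; points are libraries and bars the mean ± SD for control (n = 3), SDS10 (n = 5) and SDS30 (n = 5). SDS10 replicate 2 has the highest value, 0.332, and SDS30 replicate 2 the lowest, -0.448.

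The log2 fold changes of both durations against the same controls had a correlation of 0.568 across summits, which are not independent replicates, and 68.2% had the same sign. Libraries with no group effect, drawn 100 times from the residuals, gave a correlation of 0.631 (95% of draws between 0.280 and 0.949) and a same-sign share of 72.5%. The covariance was 0.0385 against 0.0551 simulated, so no excess over the shared controls was seen. The 3 controls are too few to be split.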

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

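The tests of summit counts over other splits, of the estimated correlation, of the other cell types' scores and of leaving out 1 library for the strong-minus-weak measure were chosen after the result was seen, and the thinning tests were chosen after correlations with log2 total reads had been seen (within groups r = 0.0523, permutation p = 0.866, for the neuronal-minus-vascular score, and r = 0.291, permutation p = 0.339, for the strong-minus-weak measure). A test without SDS10 replicate 2 and SDS30 replicate 2 together was dropped, since they hold the extremes of that measure. The criterion for the other cell types' scores and the margin for the covariate were made stricter after a first result. In 196 group values tested, 16 held a library far from the other 4 of its group, where chance gives about 9.8.

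The scores of neuronal and of vascular markers spread widely between libraries of the same group. The score of excitatory neuron markers was 0.364 in SDS10 replicate 2, against -0.111 to -0.0127 in the others, and correlated over the 13 libraries with that of glutamate receptor and postsynaptic density genes (Pearson r = 0.878, permutation p = 5e-05, adjusted p = 0.0005 over 10 relations; Spearman rho = 0.841, permutation p = 0.00057; r = 0.793 without the 2 farthest libraries; within groups r = 0.877, permutation p = 8e-05) but not significantly with endothelial and mural markers (r = -0.515, permutation p = 0.0669, adjusted p = 0.130; rho = -0.495, permutation p = 0.0885; -0.550 without the 2 farthest; within groups r = -0.506, permutation p = 0.0719). Microglia and macrophage markers went against it by rank (rho = -0.714, permutation p = 0.00807, adjusted p = 0.0305; r = -0.463, permutation p = 0.113, adjusted p = 0.161; -0.696 without the 2 farthest; within groups r = -0.459, permutation p = 0.115). Thinning every library to 4512817 reads left the within-group SD of the neuronal-minus-vascular score at 0.382, from 0.391. This argues against unequal read numbers by themselves, but thinning cannot take away noise already in a shallow library. The excitatory neuron and endothelial lists both spread more than 100% of random lists matched on level, which argues against enrichment of strong peaks as the whole cause. Enrichment stays open as a part: the strong-minus-weak measure went with that score (r = 0.552, permutation p = 0.0484, adjusted p = 0.130; rho = 0.374, permutation p = 0.208; 0.214 without the 2 farthest; within groups r = 0.570, permutation p = 0.0411, adjusted p = 0.101, and 0.402 without the 2 farthest). A lower share of neurons may contribute and stays open: the astrocyte score went with, not against, the excitatory score within groups (r = 0.566), but r was 0.232 without the 2 farthest libraries, and the oligodendrocyte score went against it (r = -0.284). The tissue dissected, which the labels do not detail, was not tested.

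The calls of gene lists between durations (adjusted p of 0.0492 for inhibitory neuron markers, 0.00209 for oligodendrocyte and myelin genes, 0.00209 for endothelial and mural cell markers, 0.0306 for ependymal and choroid plexus markers and 0.000177 for developmental transcription factors) were among 9 over the 3 comparisons. With an estimated correlation among the members of a list 0 were called, so the calls may reflect members that move together between libraries. In SDS30 against SDS10 the median log2 fold change was 0.130 in the weakest decile of summits and -0.098 in the strongest. The 5 lists called there had control medians of 31.2 to 62.95, against 97.1 over all protein-coding genes with a summit. With loess offsets, which remove trends with the level, the mean was 0.0903 for myelin genes, 0.0885 for ependymal markers and 0.00276 for developmental factors. There 0 lists were called, so those calls also depended on that trend. With the neuronal-minus-vascular score as a covariate 6 were called: 3 in SDS10 against control (from 2), 1 in SDS30 against control (from 2) and 2 between durations (from 5), where inhibitory neuron (adjusted p = 0.0501), ependymal (adjusted p = 0.0571) and endothelial markers (adjusted p = 0.0936) missed the threshold. The total lies at the bound set for that test and the score is built from the endothelial list itself, so the balance of neuronal and vascular marker signal stays open. Chance was not excluded: at least as many lists were called in 37 of 56 splits for SDS10 against control (2 real, 8 the highest other), 33 of 56 for SDS30 against control (2 and 11) and 23 of 100 drawn splits for SDS30 against SDS10 (5 and 10). A biological effect of duration was not excluded.

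Strong peaks were lower against weak peaks in SDS30 than in SDS10. The classes called were summits over 2 kb from a gene boundary (adjusted p = 0.00387), the 15227 summits with the highest mean value (adjusted p = 2.95e-13) and the X chromosome (adjusted p = 0.0261). With an estimated correlation the adjusted p was 0.0212, 0.0464 and 0.0860, and with fry 0.0616 for each. The strong-minus-weak measure was -0.448 in SDS30 replicate 2, against -0.147 to -0.0447 in the others of its group. It was 0.332 in SDS10 replicate 2, against -0.0662 to 0.0860 in the others of that group. Apart from these 2 libraries the groups overlapped and lay closer together, so the 2 carry a large part of the difference. Leaving out a measure's extremes shrinks a difference by itself, so this was not tested. Without any 1 library the difference between durations, -0.226 with all, stayed between -0.154 (without SDS30 replicate 2) and -0.260, and the call of the class with the highest values held in all 13 cases. The smallest of these differences lies within a standard error of the bound set for that test, so the part of single libraries stays open. After thinning to equal reads the difference was -0.220, which argues against unequal read numbers by themselves as the cause. SDS30 replicate 2 and SDS10 replicate 2 had only 4750679 and 5677624 reads, where the deepest library had 10887911. Thinning deeper libraries cannot take away noise already in a shallow one, so noise in these libraries stays open. At least as many classes were called in 12 of 100 drawn splits for SDS30 against SDS10 (3 real, 4 the highest other) and 15 of 56 for SDS30 against control (2 and 3), so chance was not excluded, and an effect of duration stays open. In SDS10 against control 0 classes were called, so all 56 splits give as many (3 the highest other) and the count decides nothing.

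For summits 0 were called in each comparison, so every split gives as many (56 of 56, 56 of 56 and 100 of 100) and these counts decide nothing. The highest other splits called 335, 86 and 26. The split with 335 set control replicates 2 and 3 and SDS10 replicate 2 against the other 5 libraries, which points to a structure among the libraries that does not follow the groups.

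Other lists had a library far from the rest of its group. SDS30 replicate 5 had an inhibitory neuron score of 0.18, and SDS10 replicate 4 an oligodendrocyte precursor score of -0.179. SDS10 replicate 2 had a score of 0.265 for histone deacetylases, acetyltransferases and DNA methylation enzymes. SDS30 replicate 2 had a ribosomal protein score of -0.195, and SDS30 replicate 1 a developmental transcription factor score of -0.394. Among named genes, normalised counts stood apart in SDS10 replicate 2 for Ing5 (158), Ppp1r14a (28.2), Kcnj8 (83.3) and Rsph1 (119), in SDS10 replicate 4 for Iqcj (110.1), in SDS30 replicate 5 for Vkorc1l1 (105), in SDS30 replicate 2 for Sipa1l2 (39.1) and Notch3 (68.7), and in SDS30 replicate 3 for Tspan2 (57.9).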

How the results depend on the processing

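Alternatives named as added were chosen after seeing the data. The count of 0 summits held in all of 34 alternatives for both comparisons with control and in 33 for SDS30 against SDS10; the exception, added, was DESeq2 with its filter tuned at 0.1 (4 calls), which leaves 124755 summits without an adjusted p. DESeq2's size factors, computed on the recovered reads, differed from those the deposited values carry by at most 0.0042%, so that alternative moves nothing and TMM factors (added) took its place; a correction for GC content was not run. Lists called in SDS10 against control, SDS30 against control and SDS30 against SDS10 numbered 2, 2 and 5. They were 0, 0 and 0 with loess offsets, with an estimated correlation and with fry. Exact permutation of list means (added) also gave 0, 0 and 0. Its 56 or 252 splits let no list pass alone over 27 lists, so that count decides little. Without SDS10 replicate 2 and SDS30 replicate 2 together (added) 1, 1 and 0 lists were called, and the mean of developmental transcription factors between durations turned to -0.0178. The neuronal-minus-vascular covariate (added) gave 3, 1 and 2. Within 5 kb, 1 list was called in SDS30 against control. Leaving out 1 library at a time gave 1 to 4, 1 to 3 and 0 to 5 lists. Classes called numbered 0, 2 and 3. They were 1, 0 and 1 with loess offsets, where the class with the highest mean values turned to 0.00553 and 0.00382 in both SDS30 comparisons; 0 in SDS30 against control with an estimated correlation; 0 and 0 in both SDS30 comparisons with fry; 1 and 1 in them without SDS10 replicate 2 and SDS30 replicate 2 together; and 1 in SDS30 against control within 5 kb. Leaving out 1 library at a time gave 0 to 1, 1 to 2 and 1 to 4 classes. The cause of these changes was not tested. The covariance of both durations in excess of its simulated value was -0.0166 and moved between -0.0392 and -0.0026 without 1 library.

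The replicate numbers shared by the groups do not pair the libraries: the 11 pairs with the same number had correlations of deviations between -0.287 and 0.368, and 2 of 13 libraries correlated best with their own number. With the replicate block, 0 summits were called in each comparison, lists called were 4 in SDS10 against control and 1 in SDS30 against control, and classes 1 and 1, while Nr3c1 turned to 0.011 and Kdm5b to 0.031 in SDS30 against control.

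Of 84 named gene values, none past the threshold, 14 changed sign in 31 of 1512 alternatives. With loess offsets, Arc and Sgk1 in SDS30 against control turned to 0.028 and 0.009. Leaving out 1 library moved 45 of the 84 values by over 1.5 times. Values that kept their sign ranged from 0.146 to 0.504 for Gad1 and from 0.048 to 0.463 for Bdnf in SDS10 against control, and from 0.038 to 0.39 and 0.122 to 0.44 in SDS30 against control. Others were, in SDS10 against control, -0.255 to -0.064 for Arc, 0.069 to 0.214 for Egr1, -0.306 to -0.077 for Crh, -0.517 to -0.212 for Slc17a7, -0.32 to -0.105 for Mbp and -0.371 to -0.128 for Kdm5b; in SDS30 against control, -0.193 to -0.026 for Mbp and -0.233 to -0.04 for Kdm5b. Ranges of values that changed sign were, in SDS10 against control, -0.006 to 0.39 for Npas4, -0.41 to 0.11 for Nr3c1, -0.21 to 0.10 for Fkbp5, -0.09 to 0.10 for Sgk1 and -0.468 to 0.034 for Crhr1; in SDS30 against control, -0.116 to 0.075 for Arc, -0.035 to 0.10 for Egr1, -0.39 to 0.13 for Nr3c1, -0.108 to 0.089 for Sgk1, -0.001 to 0.21 for Crh, -0.35 to 0.15 for Crhr1, -0.30 to 0.008 for Slc17a7 and -0.02 to 0.82 for H3c11. Score differences (added) ranged from -0.184 to -0.144 for myelin genes in SDS10 against control and, between durations, from -0.124 to -0.0767 for ribosomal protein genes and -0.146 to -0.0874 for the H3K4 methylation machinery. List means ranged from -0.093 to 0.183 for endothelial and mural markers in SDS30 against control and from -0.0151 to 0.0659 for inhibitory neuron markers between durations.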

Other observations

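The lists that spread most between libraries of the same group were neuronal and vascular. Glutamate receptor and postsynaptic density genes had a within-group SD of 0.216, excitatory neuron markers 0.212, endothelial and mural markers 0.208, striatal neuron markers 0.205 and monoamine receptors, transporters and enzymes 0.196, each above all of 1000 random lists matched on level. Developmental transcription factors, the list with the lowest adjusted p between durations, also spread more than all matched lists (0.168). Clustered protocadherins (0.188), GABA receptor genes (0.187) and inflammation and interferon genes (0.143) lay at percentiles of 99.7, 99.8 and 99.7. Neurotrophic factors and receptors (0.0546), oxidative phosphorylation genes (0.0572) and activity-regulated genes (0.0578) spread less than most of their matched lists, at percentiles of 6.2, 18.6 and 18.3. Striatal neuron markers, a list meant for a neighbouring tissue, followed the excitatory neuron score over the 13 libraries (Pearson r = 0.769, permutation p = 0.00164; Spearman rho = 0.703, permutation p = 0.00915; adjusted p = 0.0082 for r over 10 relations; r = 0.619 without the 2 farthest libraries; within groups r = 0.785, permutation p = 0.00112). A positive correlation gives no sign that striatal tissue took the place of cortex, and neighbouring tissue was not tested.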
